A study of Mus musculus with 10 samples.

How the data were processed

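RNA of 10 B16OVA lines was measured on 1 Affymetrix MoGene-2_0-st array each: the parent line, 3 lines from naive mice (NIMM), 3 from OVA-immunized wild-type mice (IMM) and 3 from OVA-immunized IFN-γ-deficient mice (GKO-IMM). Per the labels, total RNA was extracted with Trizol and biotinylated cRNA was prepared by the standard Affymetrix protocol. Per the file headers, 1 set of deposited columns holds raw intensity values; these were linear, summarized per transcript cluster and on nearly 1 distribution on every array, with lowest values near 17.3. The deposited normalized columns hold log2 values: the log2 of the intensity columns minus the median of each transcript cluster over the 10 arrays (largest difference 2.23e-06), and the series value table held the same values. The background correction, summarization and software are not given in the sources used here.

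The values analysed were the log2 intensities, which equal the deposited normalized values apart from 1 constant per transcript cluster, so that dim genes could be told from bright ones. No further normalization was applied, since median log2 intensities differed by less than 0.1 between arrays. Of 33793 transcript clusters, 24732 carried 1 gene symbol, 2305 several and 6756 none. Symbols were brought up to date with a RefSeq gene table on build GRCm38: 20206 were current, 2112 were updated and 1075 were in neither form. The transcript cluster with the highest mean over the 9 established lines stood for each of 23360 genes, and genes under percentile 30 of that mean (log2 intensity 4.74, intensity 26.7) were left out, which left 16352. Positions are those of the gene table.

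The 9 established lines were fitted together with limma 3.58.1 (lmFit and eBayes, trend and robust off) in R 4.3.3, in 3 groups of 3. The contrasts were IMM minus NIMM, IMM minus GKO-IMM, GKO-IMM minus NIMM, IMM minus the mean of the other groups, and an F test of any difference among the groups. Residual degrees of freedom were 6, prior degrees of freedom 5.25 and the median residual SD 0.09. Genes passed at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Adjusted p-values come from limma's moderated model across all genes, and the number of arrays limits the precision. Of 35 gene lists, also fixed in advance, 33 had enough genes tested. They were compared with all other genes by limma's camera at a preset correlation of 0.01, and again with the correlation estimated from the data. Each comparison's p-values were adjusted over the lists. Members were also adjusted over the list alone. In addition, fry tested whether the genes of a list moved, on balance, 1 way. It compares a list with no other genes. Chromosomes were tested with camera, adjusted over 63 tests (21 sets in 3 comparisons). The parent was compared without a test, by genes at least 1 log2 unit away in all 9 lines and by list medians against 10000 random lists of matched mean expression. Calculations outside limma used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, with figures from matplotlib 3.10.9.

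Named genes follow a rule set before the data were examined. In each comparison these were the 8 genes with the largest difference in each direction among those that passed without overlap between groups. Where fewer than 8 passed, those that passed and the 5 with the smallest p in that direction were taken. Up to 4 members with the smallest p of each list described were added, and 20 fixed genes, of which 19 were tested (H2-D1 shares its transcript cluster with H2-Q2). Predicted genes without a proper symbol were counted and passed over. Some genes that the rule names are not reported here. For the parent the 8 genes with the largest smallest difference in each direction were named. Timp1, Snai2, Itgb2, Postn and Des are named as single genes that passed, from lists that did not pass as sets. The genes that fell in both immunized groups against NIMM, the genes of chromosome 7 and its parts were chosen after their values were seen.

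The alternatives were quantile normalization, centring array medians, no filter, a filter at percentile 50, the mean of a gene's transcript clusters, every transcript cluster, trend and robust priors, array weights, only the groups compared and the line number as a block. Further ones were 15 subtracted from or 48 added to the intensities before log2, a minimum of 2-fold, and each line left out. Alternatives added after seeing the data were 16 added before log2, and NIMM and GKO-IMM as 1 group of 6 lines.

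The procedure was tested on simulated data of the same layout, with 200 of 16352 genes changed. It recovered 92% to 100% of genes changed by 0.5 and 100% of those changed by 1 on the log2 scale; 4.37%, 6.25% and 7.08% of the calls were unchanged genes for IMM minus NIMM, IMM minus GKO-IMM and IMM minus both. With no change simulated it called 0 genes, lists and chromosomes. The genes were simulated as independent of each other. The simulation therefore cannot show how often lists or chromosomes of correlated genes are called without a change.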

Results

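Gene expression was measured with 1 Affymetrix mouse gene array per line in 10 lines of B16OVA, a mouse melanoma line from C57BL/6 mice that carries the model antigen ovalbumin (OVA). The parent line had 1 array. The other 9 lines had each been established from a tumour: 3 from naive mice (NIMM 1, 3 and 4), 3 from OVA-immunized wild-type mice (IMM 1, 2 and 8), and 3 from OVA-immunized mice deficient in interferon-gamma (IFN-γ; GKO-IMM 1, 2 and 3). The IMM lines grew on re-challenge of OVA-immunized mice while the NIMM and GKO-IMM lines did not, so the comparisons ask what sets the IMM lines apart. Median intensities lay between 31.9 and 32.5 on every array, and the log2 intensities of any 2 arrays correlated across genes at 0.989 to 0.998, where genes are not independent replicates. The number of arrays limits the precision. Differences are given on the log2 scale with the standard error (SE) of the linear model.

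IMM lines were compared with NIMM lines to ask what growth under antigen-specific immunity left in the cells. Of 16352 genes tested, 19 rose and 51 fell in the IMM lines, and in all 70 the 3 IMM arrays lay on 1 side of the 3 NIMM arrays. Among all genes tested, 3036 were without overlap between the groups, where chance gives 10% of genes. Of the genes that passed, Blvrb fell the most and was 2.24-fold lower in the IMM lines (log2 difference -1.17 ± 0.17, SE, n = 3 lines per group, adjusted p = 0.0175). It encodes the heme-catabolic enzyme biliverdin reductase B (transcript cluster 17475580, chromosome 7, 27447978 to 27465981 in mouse build GRCm38). Among the named genes that passed, Gpm6a, a neuronal membrane glycoprotein gene, rose the most, by 0.71 ± 0.11 (n = 3 lines per group, adjusted p = 0.0247).

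Among the other genes that rose in the IMM lines against NIMM, Car6, a secreted carbonic anhydrase, rose by 0.59 ± 0.08, Timp1, an inhibitor of matrix metalloproteinases, by 0.57 ± 0.09, and the matrix protein gene Tinagl1 by 0.55 ± 0.08. The xenobiotic-sensing nuclear receptor gene Nr1i2 rose by 0.55 ± 0.10, the corepressor gene Tle5 (Aes on the array) by 0.49 ± 0.07, the microRNA gene Mir673 by 0.56 ± 0.07 and the olfactory receptor gene Olfr1359 by 0.50 ± 0.09. Among the genes that fell were the deubiquitinase gene Zranb1 (-0.85 ± 0.09, adjusted p = 0.00517) and its neighbour Ctbp2, a transcriptional corepressor (-0.74 ± 0.06, adjusted p = 0.00126). The ubiquitin ligase gene Trim68 (-0.78 ± 0.12), the efflux transporter gene Abcc2 (-0.78 ± 0.12), Adam23 (-0.77 ± 0.14), Mir669a-3 (-0.91 ± 0.10) and the olfactory receptor gene Olfr566 (-0.997 ± 0.15) fell as well. Of the 70 genes, 27 lie on chromosome 7, and all 27 fell; that chromosome holds 8.01% of the genes tested.

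None of the 19 genes fixed in advance, most of them IFN-γ pathway, antigen presentation and pigment genes, passed the test between IMM and NIMM lines by limma, and 4 were under 0.05 unadjusted. Ifngr1, which encodes the IFN-γ receptor, differed by 0.20 ± 0.07 (adjusted p = 0.255), B2m by 0.01 ± 0.07, Tap1 by 0.12 ± 0.09, and Cd274, which encodes PD-L1, by 0.07 ± 0.15. H2-K1 was at 0.16 ± 0.18, Irf1 at 0.16 ± 0.14, Jak1 at -0.03 ± 0.05 and Jak2 at 0.06 ± 0.07. Psmb8 was at -0.0034 ± 0.07, Psmb9 at -0.18 ± 0.07, Mitf at 0.09 ± 0.11 and Myc at -0.22 ± 0.08. The receptor kinase gene Axl, which lies on chromosome 7, was at -0.30 ± 0.08 (adjusted p = 0.159). The medians of the IFN-γ receptor, IFN-γ response and MHC class I lists were 0.05, 0.03 and 0.01, with camera pointing down for the response list, and no member passed when adjusted over each list alone. The pigment genes Tyr, Tyrp1, Dct, Pmel and Mlana differed by 0.19, -0.02, 0.05, 0.03 and 0.01, and under another scaling of the arrays B2m, Tyrp1 and Mlana changed sign. As a set, the 33 ribosomal protein genes tested were lower, with a median of -0.07 (adjusted p = 0.000572, limma camera; adjusted p = 0.97 with an estimated correlation). When adjusted over the list alone, 3 fell. The 36 cell cycle genes were higher as a set, with a median of 0.16 (adjusted p = 0.00344; adjusted p = 0.97 with an estimated correlation). None rose, and 0 rose and 1 fell when adjusted over the list alone. The cell cycle call ended without IMM 2 (adjusted p = 0.0712), with the line number as a block (0.725) and without NIMM 4, where the set pointed down (0.866). Of 32 extracellular matrix and adhesion genes, 1 rose, Timp1, over all genes and adjusted over the list alone.

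Leaving out any 1 line other than NIMM 4 lowered the count for IMM against NIMM to between 21 and 39, and without NIMM 4 it was 76. Without NIMM 3, 1 of 21 rose. Fitted on these 6 arrays alone, 13 genes passed.

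IMM lines were compared with GKO-IMM lines to ask what depended on host IFN-γ under the same immunization. In the IMM lines 72 genes rose and 119 fell, and all 191 were without overlap between the groups, as were 4221 of all genes tested (10% by chance). Slc44a3, a choline transporter-like gene (transcript cluster 17409893, chromosome 3, 121459528 to 121532344), was 2.81-fold higher in the IMM lines (log2 difference 1.49 ± 0.17, SE, n = 3 lines per group, adjusted p = 0.00342). The endolysosomal channel gene Mcoln3 rose by 1.28 ± 0.15, the ferroxidase gene Cp by 1.22 ± 0.13, Gpm6a by 1.14 ± 0.11 (adjusted p = 0.00114), Mxra8 by 1.12 ± 0.19 and the efflux pump gene Abcg2 by 1.03 ± 0.16. Gsta4, a glutathione transferase gene, rose by 0.97 ± 0.12 and Nr1i2 by 0.94 ± 0.10.

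Among the named genes that passed, those that fell the most against GKO-IMM overlapped those against NIMM. Blvrb was 2.52-fold lower (-1.34 ± 0.17), Olfr566 fell by 1.23 ± 0.15 on the log2 scale, Zranb1 by 1.11 ± 0.09 (adjusted p = 0.000818), Adam23 by 1.08 ± 0.14 and Trim68 by 0.99 ± 0.12. The cyclic AMP phosphodiesterase gene Pde7b fell by 0.99 ± 0.15, the amino acid transporter gene Slc7a8 by 0.94 ± 0.14 and Arfgef3 by 0.93 ± 0.13. On chromosome 7, 49 genes fell and none rose. Among 29 immune checkpoint ligand and suppressive factor genes, 2 fell, and both lie on chromosome 7. They are Tgfb1, which encodes the suppressive cytokine TGF-β1 (-0.55 ± 0.11, adjusted p = 0.0337), and Nectin2, a ligand of lymphocyte receptors (Pvrl2 on the array; -0.38 ± 0.08, adjusted p = 0.0447). The other 27 did not pass, among them Cd276 (0.28 ± 0.06, adjusted p = 0.0529) and the galectin gene Lgals9 (0.39 ± 0.09, adjusted p = 0.0654). Adjusted over the list alone, 2 rose and 2 fell.

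Genes of the unfolded protein and integrated stress response were lower as a set in IMM than in GKO-IMM lines, with a median of -0.55 over 28 genes (adjusted p = 3.74e-06, limma camera; adjusted p = 0.92 with an estimated correlation). None of the 28 passed over all genes tested, and 13 fell when adjusted over the list alone. Values of its members were -2.05 ± 0.49 for Chac1, a glutathione-degrading enzyme (adjusted p = 0.0726), -0.83 ± 0.20 for the amino acid transporter Slc7a5, -0.72 ± 0.16 for the serine synthesis enzyme Phgdh and -0.66 ± 0.16 for Slc3a2. Cholesterol biosynthesis genes were lower as a set, with a median of -0.18 over 24 genes (adjusted p = 3.21e-06; adjusted p = 0.747 with an estimated correlation). When adjusted over the list alone, 8 fell. Cell cycle genes were higher as a set, with a median of 0.25 over 36 genes (adjusted p = 1.82e-06; adjusted p = 0.92 with an estimated correlation). No cell cycle gene rose over all genes tested, 6 rose and 1 fell when adjusted over the list alone, and the ribonucleotide reductase gene Rrm1 on chromosome 7 fell (-0.60 ± 0.10, adjusted p = 0.0177). DNA damage response genes were higher as a set (median 0.09 over 39 genes, adjusted p = 0.0215; adjusted p = 0.952 with an estimated correlation). Ribosomal protein genes were lower (median -0.05, adjusted p = 0.0215; adjusted p = 0.92 with an estimated correlation). No member of either list passed, over all genes or adjusted over the list alone. The DNA damage call ended without IMM 1 (adjusted p = 0.0595), IMM 8 (0.0547) or GKO-IMM 1 (0.063), and the ribosomal call without IMM 8 (0.0781), GKO-IMM 2 (0.0641), with quantile normalization (0.0819) and with the line number as a block (0.141).

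The IFN-γ receptor, IFN-γ response and MHC class I lists did not pass between IMM and GKO-IMM lines. Their medians were 0.04, 0.03 and 0.02, where the MHC class I mean was -0.01, and 0, 0 and 1 of their members passed when adjusted over each list alone. Most members of the response list were dim, as given above. Jak2 differed by 0.21 ± 0.07 (adjusted p = 0.171), H2-K1 by -0.15 ± 0.18 and Cd274 by 0.09 ± 0.15. The melanocyte factor gene Mitf differed by 0.25 ± 0.11 (adjusted p = 0.292) and Axl by -0.27 ± 0.08 (adjusted p = 0.122). Among the other fixed genes, Tap1 was at 0.20, Tyr at 0.17, Psmb8 at 0.11, Irf1 at 0.07, Ifngr1 and Pmel at 0.06, Dct at 0.05, Psmb9 at 0.04, B2m at 0.03, Tyrp1 at -0.0044, Jak1 at -0.03, Mlana at -0.08 and Myc at -0.09. None of the 19 passed by limma, and 3 were under 0.05 unadjusted. Without IMM 2 the balance turned, with 121 genes higher and 114 lower. The count of 191 became 1208 without NIMM 4, and 114, 55, 51, 56 and 30 without IMM 1, IMM 8, GKO-IMM 1, GKO-IMM 2 and GKO-IMM 3. No NIMM array enters these differences, so leaving out NIMM 4 changed only the spread estimated over all groups and its degrees of freedom. The log2 differences of NIMM 4 from NIMM 1 and NIMM 3 had SDs across genes of 0.229 and 0.221, against 0.125 between NIMM 1 and NIMM 3. Fitted on the 6 arrays compared alone, 976 genes passed.

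**Figure D1:**
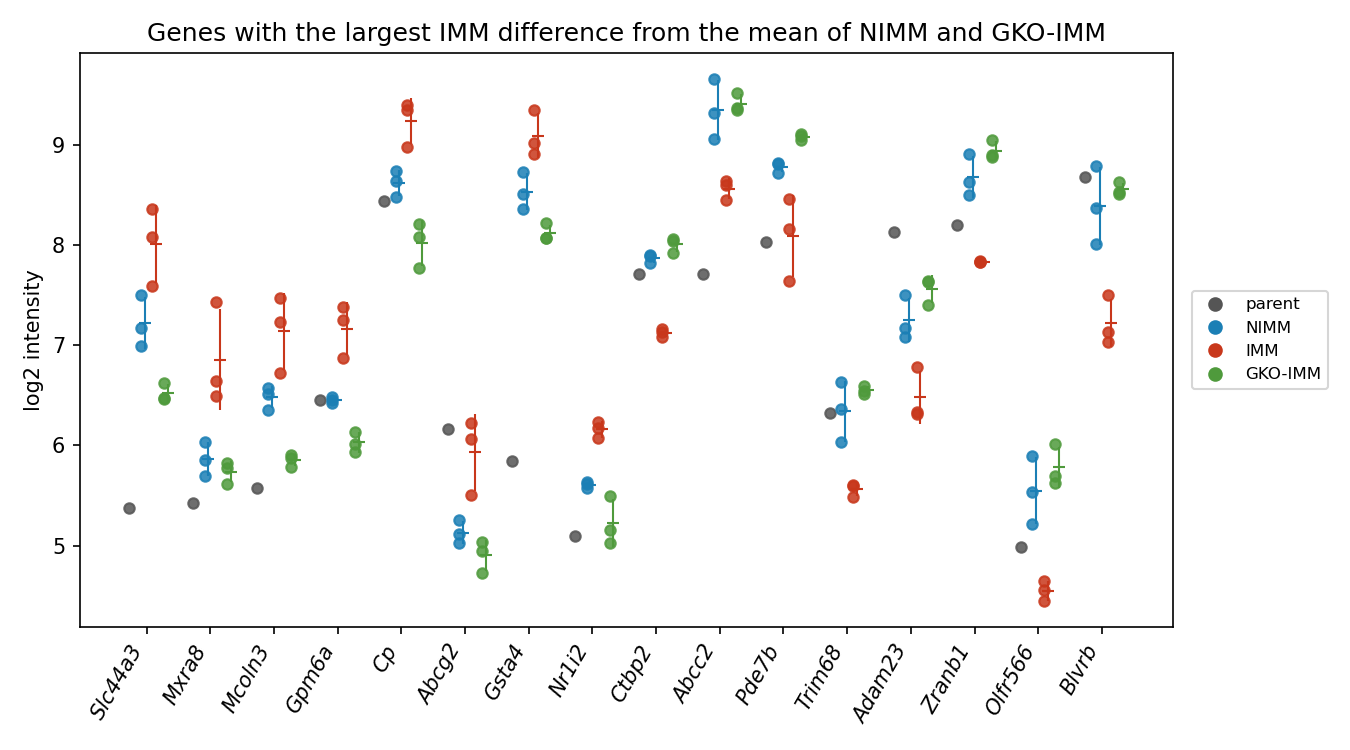
Log2 intensity of the named genes that passed without overlap and differed most between IMM lines and the mean of both other groups. Each point is 1 line (parent 1 line, other groups 3 lines each), with the mean and SD of each group of 3 beside its points. Blvrb, Olfr566, Zranb1 and Ctbp2 lay lower in the 3 IMM lines, and Slc44a3 was higher in them by 1.14 than in the mean of both other groups.

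GKO-IMM lines were compared with NIMM lines to ask what differed after growth in immunized hosts without IFN-γ. No group came from naive IFN-γ-deficient mice, so immunization and the deficiency cannot be told apart in this comparison. In the GKO-IMM lines 6 genes rose and 14 fell, all 20 without overlap, as were 3183 of all genes tested (10% by chance). The microRNA gene Mir665 rose by 0.49 ± 0.07 and the ubiquitin ligase gene Trim45 by 0.38 ± 0.06 (both adjusted p = 0.0447, n = 3 lines per group). Mir669a-3 fell by 0.88 ± 0.10, the zinc finger gene Zfp747 by 0.64 ± 0.06 (adjusted p = 0.0028), Pdzrn3 by 0.59 ± 0.09, and the small nucleolar RNA genes Snora21 and Snord66 by 0.55 ± 0.06 and 0.43 ± 0.07. Tlcd1 fell by 0.51 ± 0.08, Olfr1444 by 0.50 ± 0.08, and Postn, which encodes the matrix protein periostin, by 0.53 ± 0.08. The next genes above 0 by p did not pass, among them Rpl39l (0.32 ± 0.05, adjusted p = 0.0663), Mir1956 (0.44 ± 0.08), Mir3058 (0.32 ± 0.06) and Adam12 (0.46 ± 0.08).

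Cholesterol biosynthesis genes were higher as a set in GKO-IMM than in NIMM lines, with a median of 0.21 over 24 genes (adjusted p = 3.18e-07; adjusted p = 0.963 with an estimated correlation). None passed over all genes tested and 8 rose when adjusted over the list alone. Fdft1 and Fdps were each at 0.43 ± 0.09 and Hmgcs1 at 0.40 ± 0.07. Unfolded protein and integrated stress response genes had a median of 0.27 over 28 genes (adjusted p = 0.00435; adjusted p = 0.963 with an estimated correlation), with Chac1 at 1.68 ± 0.49 and the cystine transporter gene Slc7a11 at 1.62 ± 0.55. NF-κB target genes had a median of 0.13 over 21 genes (adjusted p = 0.0102; adjusted p = 0.963 with an estimated correlation), with Nfkb1 at 0.39 ± 0.14 and Rel at 0.26 ± 0.08. No gene of these last lists passed, over all genes or adjusted over the list alone. The stress response call ended without NIMM 1 (adjusted p = 0.826) or NIMM 3 (0.541), and the NF-κB call without NIMM 1 (0.156) or NIMM 3 (0.107). H2-K1 differed by 0.31 ± 0.18, Psmb9 by -0.21 ± 0.07 (adjusted p = 0.205) and Axl by -0.03 ± 0.08. Among the other fixed genes, Ifngr1 was at 0.14, Irf1 at 0.10, Mlana at 0.09, Tyr at 0.03, Jak1 at 0.01, Dct at 0.00067, Tyrp1 at -0.01, B2m and Cd274 at -0.02, Pmel at -0.03, Tap1 at -0.08, Psmb8 at -0.11, Myc at -0.13, Jak2 at -0.15 and Mitf at -0.16. None of the 19 passed by limma, and 1 was under 0.05 unadjusted.

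The count of 20 became 1264 without NIMM 4, where 691 rose and 573 fell, 7 without NIMM 1, and 6 without NIMM 3, IMM 8, GKO-IMM 1, GKO-IMM 2 or GKO-IMM 3. NIMM 4 lay beside the GKO-IMM lines on the main axis of variation. Principal component 1, with 36.7% of the variance, placed NIMM 4 at 15.04, the GKO-IMM lines between 10.8 and 12.5, and the other 6 lines between -11.1 and -5.82.

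**Figure D2:**
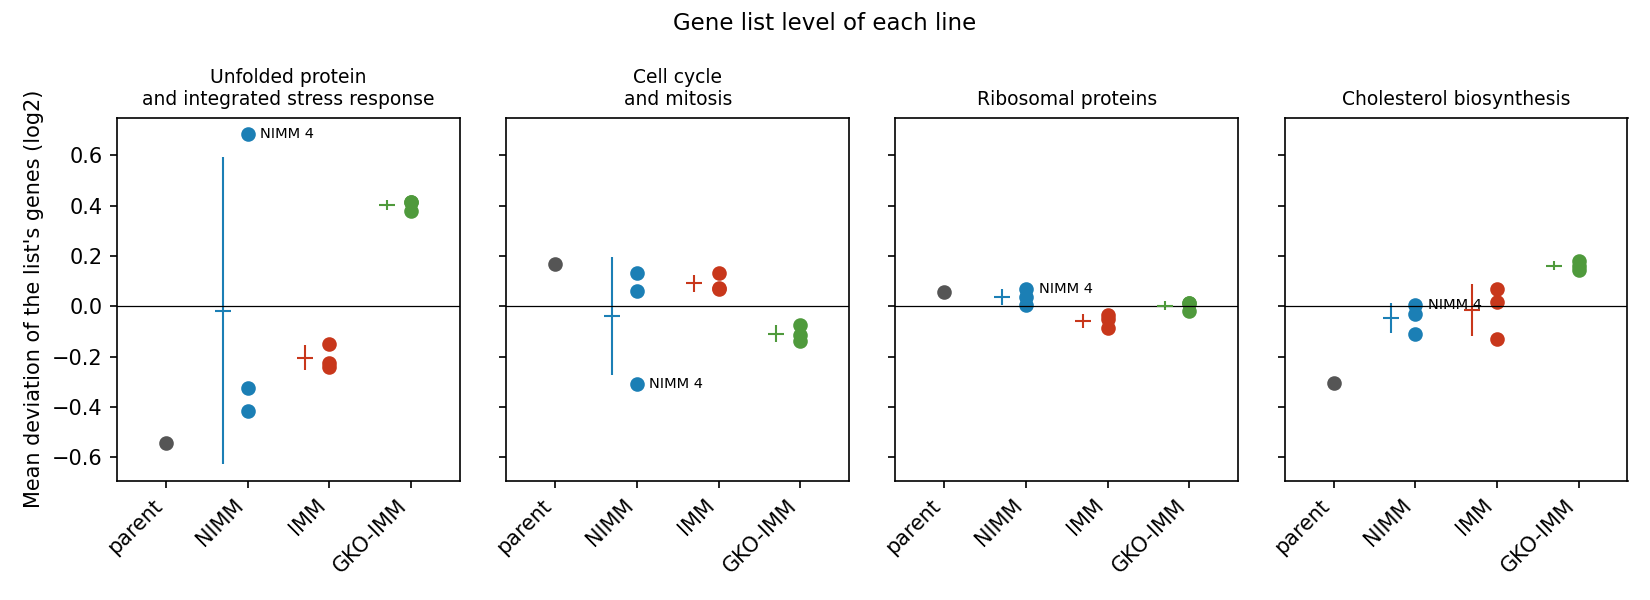
Mean log2 deviation of the genes of 4 lists in each line from the mean of the 10 arrays, 1 point per line, with the mean and SD of each group of 3 lines beside its points. For the unfolded protein and integrated stress response, NIMM 4 stood at 0.68 and the GKO-IMM lines between 0.38 and 0.42, against -0.41 and -0.32 in NIMM 1 and NIMM 3 and -0.54 in the parent.

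IMM lines were then set against the mean of NIMM and GKO-IMM lines, the contrast that follows the growth on re-challenge. In the IMM lines 50 genes rose and 82 fell, and in 119 of these 132 genes the IMM arrays lay on 1 side of the 6 others; 1111 of all genes tested did so, where chance gives 2.38%. Slc44a3 rose by 1.14 ± 0.15, Mxra8 by 1.06 ± 0.17, Mcoln3 by 0.97 ± 0.13, and Gpm6a by 0.92 ± 0.10 (n = 3 against 6 lines, adjusted p = 0.00201 for Gpm6a and 0.0201 for Mxra8). Cp rose by 0.92 ± 0.11, Abcg2 by 0.91 ± 0.13, Gsta4 by 0.77 ± 0.10 and Nr1i2 by 0.74 ± 0.09. Blvrb fell by 1.25 ± 0.14 on the log2 scale, Olfr566 by 1.11 ± 0.13, Zranb1 by 0.98 ± 0.08, and Adam23 by 0.93 ± 0.12. Trim68 fell by 0.88 ± 0.10, Pde7b by 0.84 ± 0.13, and Abcc2 and Ctbp2 by 0.81 ± 0.11 and 0.81 ± 0.05 (adjusted p = 0.000105 for Ctbp2). Chromosome 7 held 43 of the 82 genes that fell.

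Among immune genes in this contrast, Cd276, an immune checkpoint ligand, rose by 0.27 ± 0.05 and Tgfb1 fell by 0.47 ± 0.09 (both adjusted p = 0.0392), 2 of 29 members of their list. Adjusted over the list alone, 3 rose and 2 fell. Timp1 rose by 0.61 ± 0.08 (adjusted p = 0.00596) and Snai2, a neural crest transcription factor gene, fell by 0.41 ± 0.08 (adjusted p = 0.0392). Of the sets, cell cycle genes were higher (median 0.18, adjusted p = 7.59e-06), as were DNA damage response genes (median 0.08, adjusted p = 0.0277). With an estimated correlation both had adjusted p = 0.975. Stress response genes (median -0.40, adjusted p = 0.000175), ribosomal protein genes (median -0.05, adjusted p = 0.000507) and cholesterol genes (median -0.07, adjusted p = 0.0214) were lower. With an estimated correlation the ribosomal call had adjusted p = 0.699 and the other 2 adjusted p = 0.975. Against NIMM alone the stress response list did not pass (median -0.19, adjusted p = 0.122), and its direction changed with the line left out. At the preset correlation it was lower in IMM lines without NIMM 1 (adjusted p = 4.75e-05) or NIMM 3 (0.000273), and higher without NIMM 4 (0.000598) and with the line number as a block (0.00168), which leaves out NIMM 4. Rrm1, a member of the cell cycle list, fell (-0.55 ± 0.09). Adjusted over the list alone, 3 cell cycle genes rose and 1 fell, 0 DNA damage response genes passed and 4 stress response, 5 ribosomal and 1 cholesterol genes fell. The cholesterol call ended without IMM 2 (adjusted p = 0.724) or NIMM 3 (0.0557), and the DNA damage call without NIMM 4 (0.128), IMM 1 (0.083), IMM 2 (0.0631) or IMM 8 (0.0607). With the line number as a block both ended (0.124). Axl, in the proximal part of chromosome 7 whose genes were lower together in the IMM lines, differed by -0.28 ± 0.07 (adjusted p = 0.0943). Its p was the lowest among the 19 genes fixed in advance. None of these passed by limma, and 2 were under 0.05 unadjusted. Values of others were Tyr at 0.18, Mitf at 0.17, Tap1 at 0.16, Ifngr1 and Jak2 at 0.13, Irf1 at 0.11, Cd274 at 0.08, Dct, Pmel and Psmb8 at 0.05, B2m at 0.02, H2-K1 at 0.01, Tyrp1 at -0.01, Jak1 at -0.03, Mlana at -0.04, Psmb9 at -0.07 and Myc at -0.15.

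Without IMM 2, 79 genes rose and 61 fell, so the balance turned. The count of 132 became 304 without NIMM 4, and 52, 41, 54, 64 and 39 without IMM 1, IMM 8, GKO-IMM 1, GKO-IMM 2 and GKO-IMM 3. Any difference among the 3 groups was found in 167 genes, 43 of them on chromosome 7. That count became 1442 without NIMM 4, 111 and 85 without NIMM 1 and NIMM 3, 86 and 40 without IMM 1 and IMM 8, and 41, 53 and 32 without GKO-IMM 1, GKO-IMM 2 and GKO-IMM 3.

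Genes that fell in IMM lines against both other groups numbered 20, and 16 of these lie on chromosome 7. Genes that rose against both numbered 8. Both comparisons use the same 3 IMM arrays, so shared calls are expected in part. Across genes the 2 sets of differences correlated at 0.617, where the 3 IMM arrays they share gave 0.50 in simulated data without any change. The covariance of the differences was 0.0137, against 0.00466 in the simulated data. The 3 IMM arrays cannot be split into parts of at least 2 arrays each, so part of the excess may come from the arrays shared. Without NIMM 4 the correlation was 0.286, under the 0.447 that the shared arrays give by design without any change, so the excess was absent without that line. NIMM lines set apart from both immunized groups shared 9 genes: 8 fell in both, among them Mir669a-3, Snora21, Snord66, Zfp747 and Olfr1444, and 1 rose in both. Across genes these 2 sets of differences correlated at 0.211, under the 0.50 that the shared NIMM arrays gave in simulated data.

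Chromosome 7 as a set was lower in IMM lines against NIMM (median -0.03 over 1309 genes, adjusted p = 0.000225) and against GKO-IMM (median -0.04, adjusted p = 5.7e-05); with an estimated correlation both had adjusted p = 0.0491. Chromosome 17 was lower in IMM against GKO-IMM lines (median -0.04 over 803 genes, adjusted p = 5.7e-05; adjusted p = 0.146 with an estimated correlation) and higher in GKO-IMM against NIMM lines (median 0.05, adjusted p = 0.0153; adjusted p = 0.447 with an estimated correlation). These 4 of 63 tests passed and did so without any 1 of the 9 lines.

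**Figure D3:**
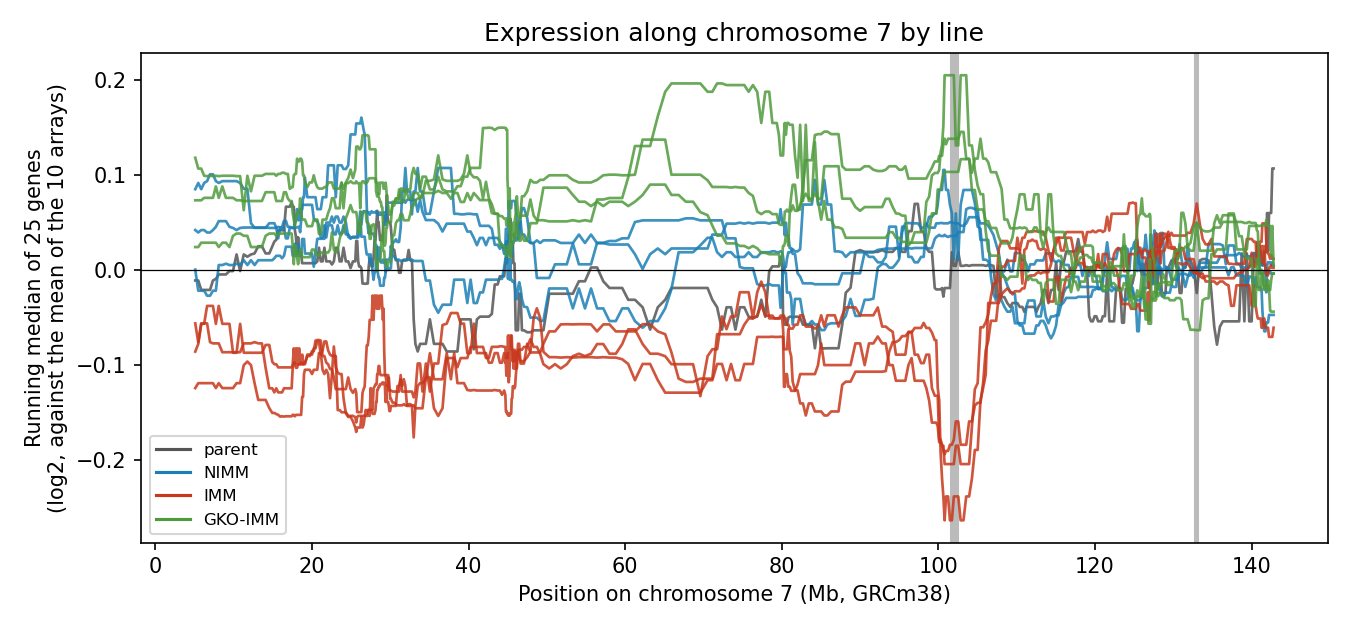
Expression along chromosome 7 (position in Mb, GRCm38) as the running median over 25 neighbouring expressed genes of each line's log2 level, against the mean of the 10 arrays, 1 curve per line coloured by group. Expressed genes had a mean log2 intensity of at least 6.5 over the 9 established lines, and dimmer genes are not shown. Grey bands mark, to scale, the 10 genes from Clpb to Rrm1 and the 4 genes from Eef1akmt2 to Ctbp2, whose medians over all members were -0.43 and -0.75 in IMM lines against the mean of both other groups.

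All 9 established lines differed from the parent line in 9 genes by at least 1 log2 unit; the parent had 1 array, so no test was run. Gsta4 was higher by 2.73 on average (at least 4.66-fold in every line), the interferon-inducible chemokine gene Cxcl10 by 2.02, Slc44a3 by 1.88, the growth factor receptor gene Pdgfrb by 1.48 and Gbgt1 by 1.42. The chemokine gene Ccl5 was lower, at -1.94 on average, as were Fbxo2 at -1.93, Ecm1 at -1.64 and Serpinb9b, a serine protease inhibitor, at -1.59. Taking any other line as the reference gave 0 or 1 such gene. Next in size were Tinagl1 (1.40), Fkbp10 (1.17) and Arl11 (1.11) above the parent, and Cd68 (-1.27), Dpysl3 (-1.23), Postn (-1.10) and Tspan17 (-0.93) below it.

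Hypoxia and glycolysis genes lay above the parent in median by 0.49 (31 of 31 genes), unfolded protein and integrated stress response genes by 0.49 (27 of 28) and cholesterol biosynthesis genes by 0.38 (21 of 24), each at percentile 100 of 10000 random lists of matched expression. These percentiles are no test: the parent is 1 array, and random lists ignore the correlation within a list, estimated at 0.636, 0.827 and 0.213 among the 9 lines. Cell cycle genes lay below it with a median of -0.18 (2 of 36 above). IFN-γ response genes were at 0.08 and MHC class I genes at 0.08, at percentiles 99.3 and 99.0 of the random lists, and type I interferon genes were at -0.07, at percentile 0.35.

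Of 62 markers of other cell types tested, none passed between IMM and NIMM lines by limma, and 10 were under 0.05 unadjusted. Between IMM and GKO-IMM lines the leukocyte integrin gene Itgb2 rose (0.54 ± 0.10), Postn rose (0.66 ± 0.08) and the muscle gene Des fell (-0.45 ± 0.09), which is 4.84% of the markers, against 1.17% of all genes tested. Between GKO-IMM and NIMM lines 1 marker, Postn, passed (1.61%, against 0.122% of all genes). The mean level of macrophage markers was 0.06 in IMM against -0.05 in GKO-IMM and -0.02 in NIMM lines (fry adjusted p = 0.0148 and 0.0243), and that of fibroblast markers 0.06 against -0.05 and -0.0071 (0.0293 and 0.0859). By camera neither list passed against GKO-IMM or NIMM (adjusted p = 0.141 and 0.34 for macrophage markers, 0.091 and 0.37 for fibroblast markers). Most of these markers were dim, with mean log2 intensities of 5.26 and 5.79. Of 11 macrophage and 12 fibroblast markers, 1 each lay over 7. The lists that camera called in these comparisons did not pass by fry. Their fry adjusted p was 0.195 to 0.505 against GKO-IMM. Against NIMM it was 0.0859 for ribosomal proteins and 0.633 for the cell cycle.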

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

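The tests of NIMM 4 and of the transcript clusters without a symbol were chosen after those results were seen. Transcript clusters with no gene symbol stood outside the comparisons, and 79 of 3047 passed between IMM and NIMM lines, 10 between IMM and GKO-IMM lines and 99 between GKO-IMM and NIMM lines.

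The clusters without a symbol set NIMM lines apart from both immunized groups: 48 passed in both comparisons, 36 lower and 12 higher. Both comparisons share the 3 NIMM arrays, so agreement in sign is no evidence by itself. They made up 1.58% of the clusters without a symbol, against 0.164% of 18947 named ones, a ratio of 9.63. A growth in immunized hosts may have left this difference, and so may arrays or RNA handled in separate rounds. The parent lay 0.101 of the way from NIMM to the other groups in median, on the NIMM side, which either explanation allows. No handling dates are given in the sources used here, so the host and the handling cannot be told apart for these clusters.

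NIMM 4 lay beside the GKO-IMM lines on principal component 1 and in stress response genes, where it stood at 0.68 against 0.38 to 0.42 in the GKO-IMM lines. RNA of another cell type is argued against for the types listed: the markers with the highest mean difference from NIMM 1 and NIMM 3 in NIMM 4, those of keratinocytes and epithelium, were at 0.0633, and the highest mean plus SE of any type was 0.0988, far under the stress response shift. A mislabelled line was examined over 113 clusters that part NIMM 1 and NIMM 3 from both other groups. In them NIMM 4 lay 0.339 of the way to the GKO-IMM mean in median, with quartiles of 0.126 and 0.6. That place between the groups leaves a wrong label and a line of its own state open. The chromosome 17 median was -1.8e-05 in NIMM 4 and 0.03 in each GKO-IMM line, and no biological explanation was tested, since the labels name none for a single line.

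Of the genes named between IMM and GKO-IMM lines, 16 had differences from NIMM of opposite sign in the IMM and the GKO-IMM lines, and the difference between IMM and GKO-IMM lines itself passed the test. Against NIMM by limma, 7 of the 16 passed in the IMM lines and 0 in the GKO-IMM lines, where 10 had an unadjusted p under 0.05, so opposite changes are not shown. Those higher in the IMM lines were Abcg2 (1.03), Cp (1.22), Gpm6a (1.14), Gsta4 (0.97), Mcoln3 (1.28), Mxra8 (1.12), Nr1i2 (0.94) and Slc44a3 (1.49). Those lower were Adam23 (-1.08), Arfgef3 (-0.93), Blvrb (-1.34), Olfr566 (-1.23), Pde7b (-0.99), Slc7a8 (-0.94), Trim68 (-0.99) and Zranb1 (-1.11). The medians of 4 lists that passed between IMM and GKO-IMM lines also had opposite signs against NIMM: the cell cycle list (0.25), the DNA damage response list (0.088), the unfolded protein and integrated stress response list (-0.55) and the ribosomal protein list (-0.046). None of these 4 passed with an estimated correlation. For ribosomal proteins the GKO-IMM minus NIMM median was 0.0013 and the mean -0.03, so that list did not rise. For the other 3 the opposite directions depend on single NIMM lines. For the stress response in IMM against NIMM, camera at the preset correlation pointed down without NIMM 1 (adjusted p = 4.75e-05) and NIMM 3 (0.000273) and up without NIMM 4 (0.000598). Without NIMM 4 it pointed down in that comparison for the cell cycle (adjusted p = 0.866) and DNA damage (0.842), as in GKO-IMM against NIMM. Without NIMM 3 it pointed up for the cell cycle and DNA damage in GKO-IMM against NIMM (both adjusted p = 0.939), as in IMM against NIMM (3.16e-08 and 0.00383).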

How the results depend on the processing

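The alternatives with 16 added and with NIMM and GKO-IMM as 1 group were chosen after seeing the data. Where no cause is given for a changed value, the cause was not tested. Signal over background limits dim genes, whose changes an offset in the intensities makes smaller. Quantile normalization, centring, the mean of a gene's clusters and trend and robust priors left every count of genes and, where run, of lists within 1.5 times, and no scaling moved the median of all genes by over 0.1.

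The counts of genes are given in the order IMM minus NIMM, IMM minus GKO-IMM, GKO-IMM minus NIMM, IMM minus both, and any difference. They were 33, 91, 9, 82 and 101 with no filter, where more genes were tested, and 45 and 7 for the first and the third with a filter at percentile 50. Every transcript cluster tested gave 203, 182 and 340 for the first, the third and the last. Array weights gave 167, 1037, 1217, 265 and 1431. Only the groups compared gave 13 and 976 for the first and the second. With 15 subtracted the second, the fourth and the last were 90, 52 and 98. With 48 added the first, the third and the last were 33, 5 and 101, and with 16 added the third was 6. A minimum of 2-fold left 1, 11, 0, 4 and 10, since a size was asked for as well. At the other end, 2300, 2810, 2280, 2688 and 3011 genes had an unadjusted p under 0.05 in the limma fit. NIMM and GKO-IMM as 1 group gave 49 for the fourth. Among scalings and offsets, the share of higher genes moved by 10 points or more with 15 subtracted (27.1% to 37.1%, IMM minus NIMM) and, for GKO-IMM minus NIMM, with 48 added (30% to 20%) and 16 added (16.7%). For GKO-IMM minus NIMM more genes rose than fell with array weights (664 and 553), the line number as a block (518 and 397) and without NIMM 4 (691 and 573).

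The line numbers do not pair the lines: same-number correlations were -0.135 to 0.12 over 5 pairs, others -0.116 to 0.147 over 22. As a block over the 7 lines whose number occurs in over 1 group, which leaves out NIMM 4 and IMM 8, they gave 29, 586, 915 and 927 genes for the first, the second, the third and the last comparison, and 4, 7 and 3 lists for IMM minus NIMM, GKO-IMM minus NIMM and IMM minus both. With an estimated correlation 0 lists passed in each of the 4 comparisons and 2 chromosome tests passed. The other deposited table held the same values, and for IMM minus both the groups compared are all groups, so these alternatives gave no value.

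Each line left out gave ranges of 21 to 76, 30 to 1208, 6 to 1264, 39 to 304 and 32 to 1442 genes, each highest without NIMM 4 and lowest without NIMM 3, GKO-IMM 3, GKO-IMM 3 (with 4 others), GKO-IMM 3 and GKO-IMM 3. Lists ranged from 2 to 5 for IMM minus NIMM (5 without NIMM 1, 4 without NIMM 3 or NIMM 4), 3 to 7 for IMM minus GKO-IMM (3 without IMM 8) and 1 to 6 for GKO-IMM minus NIMM (1 without NIMM 1 or NIMM 3, 6 without NIMM 4, 5 without GKO-IMM 3). The shared correlation ranged from 0.286, without NIMM 4, to 0.706, and genes apart from the parent from 9 to 11.

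Of 4165 alternative values of named genes, 3737 kept their direction and side of the threshold, 252 no longer passed, 112 came to pass and 64 changed sign. All 64 belong to fixed genes that passed in no comparison, with log2 differences under 0.2 in size. Quantile normalization gave Tyrp1 0.023 for IMM minus NIMM, Tyrp1 0.041 for IMM minus GKO-IMM, Dct -0.036 and Jak1 -0.025 for GKO-IMM minus NIMM, Tyrp1 0.032 for IMM minus both. Centring array medians gave B2m -0.0067 and Mlana -0.0082 for IMM minus NIMM, Dct -0.0067 and Jak1 -0.0017 for GKO-IMM minus NIMM, H2-K1 -0.0066 for IMM minus both. Array weights gave Irf1 -0.013 and Tyrp1 0.0031 for IMM minus GKO-IMM, B2m 0.0079, Dct -0.0035 and Tyr -0.031 for GKO-IMM minus NIMM. The line number as a block gave Tyrp1 0.011 for IMM minus NIMM, Tyrp1 0.0063 for IMM minus GKO-IMM, B2m 0.047, Cd274 0.087, Tyr -0.027 and Tyrp1 0.0042 for GKO-IMM minus NIMM, Tyrp1 0.0084 for IMM minus both. With 1 line left out, sign changes for IMM minus NIMM lay within B2m -0.045 to 0.052, Cd274 -0.10 to 0.28, H2-K1 -0.012 to 0.36, Irf1 -0.039 to 0.29, Mitf -0.056 to 0.19, Mlana -0.0096 to 0.022, Pmel -0.0029 to 0.063 and Psmb8 -0.066 to 0.031. For IMM minus GKO-IMM the ranges were B2m -0.027 to 0.0698, Cd274 -0.083 to 0.29, H2-K1 -0.33 to 0.044, Irf1 -0.13 to 0.20, Psmb9 -0.000196 to 0.064 and Tyrp1 -0.021 to 0.0073. Those for GKO-IMM minus NIMM were B2m -0.047 to 0.019, Cd274 -0.099 to 0.046, Dct -0.015 to 0.028, Jak1 -0.012 to 0.027, Tyr -0.077 to 0.10 and Tyrp1 -0.023 to 0.0049. For IMM minus both they were B2m -0.036 to 0.061, Cd274 -0.091 to 0.29, H2-K1 -0.17 to 0.20, Irf1 -0.086 to 0.25 and Tyrp1 -0.022 to 0.000601.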

Other observations

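The tests of chromosome 7 were chosen after the result was seen; the counts over other splits of the lines were planned. Genes on the proximal part of chromosome 7 were lower together in the IMM lines. Of 324 expressed genes up to the end of Rrm1 (102469771), 297 lay lower in IMM lines than in the mean of both other groups and 29 fell. Of the 179 genes after it, 80 lay lower and 4 fell. The median level of those 324 genes was -0.12, -0.10 and -0.11 in IMM 1, 2 and 8, between 0.01 and 0.05 in the NIMM lines, between 0.05 and 0.10 in the GKO-IMM lines and 0.0032 in the parent. Without the 14 genes of the runs described next, chromosome 7 lay lower in IMM lines against NIMM and against GKO-IMM, with medians of -0.027 and -0.034 over 1295 genes. After the end of Rrm1 the medians of all 10 lines lay between -0.008 and 0.0119.

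Within it, 10 neighbouring expressed genes fell between 101663596 and 102469771, without a gap when dimmer genes are passed over. They were Clpb, Inppl1, Lamtor1, Numa1, Rnf121, Nup98, Pgap2, Rhog, the calcium sensor gene Stim1 and Rrm1, with a median of -0.43. Their median level was -0.47, -0.53 and -0.45 in IMM 1, 2 and 8 and between -0.14 and 0.13 in the other 7 lines. A separate run of 4 genes, Eef1akmt2, Abraxas2, Zranb1 and Ctbp2, between 132827457 and 133124009, had a median of -0.75 and stood at -0.75, -0.79 and -0.77 in the IMM lines. The parent stood at -0.34 and NIMM 1 at -0.26, NIMM 3 and NIMM 4 at -0.09 and -0.0090, and the GKO-IMM lines between 0.08 and 0.17.

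A chance order of the genes is argued against: 0 of 1000 shuffled orders gave a run of 10, and the longest in them was 3. A stress state shared by NIMM 4 and the GKO-IMM lines is argued against as well for the proximal part. Without NIMM 4, its 314 genes outside the runs were lower in IMM than in NIMM lines, with a median of -0.123 and an upper quartile of -0.0497. A single segment that holds both runs is argued against, since the 127 expressed genes between them had a median of 0.0257 and a lower quartile of -0.0489. A candidate explanation is separate segments shared by the IMM lines, such as copies lost before or during growth in the host. Genes of the runs found without 1 IMM line were lower in that line too, with medians of -0.568, -0.597 and -0.584 in IMM 1, 2 and 8. Of the run of 10 only 3, 6 and 4 genes were then found, with medians of -0.31, -0.53 and -0.38 in the line left out. The run of 4 was found each time (-0.75, -0.79 and -0.77). The same 6 NIMM and GKO-IMM lines served to find the genes and as the reference, which can make another line look lower. The parent, which entered no fit, stood at -0.14 in the run of 10 and -0.34 in the run of 4. RNA does not show DNA, and host immunity as the source stays open as untested. If the IMM lines share segments by descent, they may not be 3 independent lines, which bears on each IMM count.

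Other splits of the lines test whether the groups matter to a count. For IMM minus both, 2 of 100 splits drawn from 840 gave as many genes as the real one (132; highest other 191, from NIMM 4, GKO-IMM 1 and GKO-IMM 3 against the rest). For any difference among groups 1 of 100 drawn from 280 did, the real one (167; highest other 76). Both shares lie under 0.05, which argues against chance as far as the lines are independent. That independence is in doubt for the IMM lines, and for IMM minus both another split gave more genes than the real one. Chance is therefore not excluded. The pairwise comparisons have 10 splits, too few for a share under 0.05: in each the real split, 1 of 10, gave the highest count (70, 191 and 20; highest other 0). For lists in the pairwise comparisons 10, 2 and 6 of 10 splits gave as many as the real 2, 5 and 3 (highest other 9, 5 and 9). The 10 splits are again too few for a share under 0.05. Other splits gave as many lists in each comparison, so chance cannot be excluded for these counts. Chance cannot be excluded for the lists of IMM minus both (5; 40 of 100 splits, highest other 9), for the chromosome tests (4; 18 of 100, highest other 5) or for the shared correlation (0.617; 21 of 100, highest other 0.831).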
